A study of Mus musculus with 6 samples.

How the data were processed

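The deposited table gives 1 value per gene and library for 6 mouse heart libraries. Per the labels' protocols, poly-A RNA was purified and libraries were made with a directional kit. The submitters' processing notes name bcl2fastq, FastQC, Trim Galore, STAR and edgeR and the build mm10, with no versions; the read counter and the gene annotation are not given in the sources used here. Per the file headers and file name, the deposited values are log2 CPM that the authors scaled by TMM, and a small count was added before the log2, since every library has the same lowest value of -4.04. Log2 values of low genes are drawn toward that floor, so their fold changes are understated.

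The low values allowed the read depth to be recovered. After the shared floor of 0.061 CPM was subtracted on the linear scale, 100% of the values below 200 steps in each library were whole multiples of 1 step, within a tolerance of 0.02 reads. The step gives what 1 read is worth, from 0.0229 to 0.0373 CPM. Total reads in the listed genes were 28624427 and 32285438 in untreated replicates 8 and 9, 35895896 and 29028033 in rivaroxaban replicates 14 and 15, and 27176892 and 43798222 in dabigatran replicates 10 and 12. The authors' scaling factors implied by these totals lay between 0.986 and 1.01. The top 10 genes took between 13.2% and 13.7% of the reads of each library. Reads without molecular identifiers are not independent molecules. Replicates were not copies of each other: over 12347 genes with a mean of at least 50 reads, the chi-square per gene between replicates was 7.85 for the untreated, 5.95 for the rivaroxaban and 9.04 for the dabigatran pair, where counting error alone would give about 1. For rivaroxaban replicate 15 it was 7.20 against dabigatran replicate 12 and 8.94 against dabigatran replicate 10, both below the dabigatran pair. For rivaroxaban replicate 14 these values were 10.5 and 12.3. On this measure the drug groups were thus not clearly separate. Between treated and untreated libraries it lay between 11.0 and 17.2.

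Samples were grouped by the treatment in their labels, with 2 libraries per group, and every column was used. Genes with a mean log2 CPM of at least 0 over all libraries were tested, 12981 of 16229. A linear model with 3 group means was fitted to all 6 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend), which leaves 3 residual degrees of freedom and gave 7.75 prior degrees of freedom. The libraries of a group thus share an estimate of spread with the other groups. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within each comparison, and the threshold was 0.05. Intervals are at 95%. Fold changes given as a share of a level are the antilog of the log2 difference.

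40 gene lists for pathways and cell types were fixed before the data were examined, and 36 had at least 5 tested members. Of their 868 entries, 749 matched by symbol and 2 by Entrez number through the RefSeq gene table of GRCm38.p6, and 651 were tested. Lists were tested with camera in limma, preset inter-gene correlation 0.01, adjusted over the lists. Camera compares a list with all other genes; fry tests whether the genes of a list move, on balance, one way. With an estimated correlation no list passed in any comparison. Correlation between genes alone does not account for this loss. Camera then tests on the 3 residual degrees of freedom of the fit. With a preset correlation it uses nearly as many as there are tested genes. Failing with an estimated correlation can thus reflect the few libraries as well as correlation. For immediate early genes the estimated correlation was -0.0218, below the preset 0.01. Their unadjusted camera p with rivaroxaban still moved from 2.5e-10 to 0.00587. With fry, immediate early genes passed for both drugs against untreated (adjusted p = 0.0343 and 0.0289) and no list between the drugs.

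The genes named were chosen by a rule fixed before the data were examined. Among genes past the threshold whose libraries do not overlap between the groups, with a mean log2 CPM of at least 1 in a group and an ordinary gene symbol, the 12 largest rises and 12 largest falls of each comparison were taken. Where fewer than 6 qualified, the smallest p-values filled up to 6 and are given as not passing. Up to 4 members of each passing list and 8 coagulation genes were added. Other genes, such as list members that were called or that differ from the rest of their list, were chosen after their values were seen. Libraries of 2 against 2 do not overlap in 33.3% of genes by chance; 50.6%, 43.6% and 39.7% of genes did not overlap for rivaroxaban and dabigatran against untreated and for the drugs against each other. Coordinates are from GENCODE M21 on GRCm38, the assembly mm10 stands for, matched by Ensembl identifier for all 132 named genes. A few genes that met the rule are not reported here and were not replaced; the tests and counts include them.

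The test was checked on simulated data: reads were drawn for the 12981 genes with 200 genes changed between the rivaroxaban and untreated groups. It recovered 35 and 36 of 50 genes raised or lowered by a log2 of 0.5 (70% and 72%). Of those raised or lowered by 1 it recovered 44 and 48 of 50 (88% and 96%). In the same comparison it called 17 of 12766 unchanged genes. These false calls are to be set against the correct calls, not against all unchanged genes. For dabigatran against untreated, where nothing was changed, that draw gave 0 calls. The spread of each gene was drawn from the fit with the trend, so the trend itself was not checked. Camera called a simulated list of shifted genes and did not call an unchanged one. Genes were drawn independently of each other there, so this does not check list calls among correlated genes. In the data the estimated correlation reached 0.71 for heat shock proteins. The shared untreated libraries were handled by 100 simulated sets of unchanged groups, in which genes were also drawn independently of each other. Enrichment used one-sided Fisher tests of the Gene Ontology terms in the table, with 10 to 300 tested genes per term.

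Alternatives tried were other filters on low genes, 1 CPM added before the log2, equal medians and quantile normalization in place of the authors' scaling, limma without the trend, with robust priors or with library weights, only the 4 libraries compared, an adjusted p of 0.10, and leaving out each library. Limma voom on the recovered reads, with the authors' effective library sizes, was added after the data were seen. Fits of each drug against a different untreated library, with the untreated libraries as separate groups, were added later as well.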

Results

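Poly-A RNA was sequenced from 6 heart samples of male C57BL/6 mice, a common inbred laboratory strain. The protocol text describes every sample as infarcted tissue together with the tissue around it. However, Spp1, S100a8, S100a9 and Il1b, usually abundant in freshly infarcted heart, were near the floor in every group. The series is about ischemia-reperfusion injury of the heart, in which blood flow to the muscle is stopped and restored. The labels do not say whether the untreated mice had surgery. 2 samples came from untreated mice, 2 from mice given rivaroxaban and 2 from mice given dabigatran. Rivaroxaban is an oral inhibitor of coagulation factor Xa and was given at 3 mg/kg for 7 days. Dabigatran inhibits factor IIa, thrombin, and was given at 10 mg/kg for 7 days. The drugs were therefore compared at different doses, 1 dose each. The libraries held between 27176892 and 43798222 reads in the listed genes, and the median tested gene had between 594 and 975 reads. Expression is given as log2 CPM, the log2 of reads scaled to a common library size, and 12981 of 16229 listed genes were tested. The labels do not say whether the samples of a group came from separate mice, so the p-values measure only the spread between these samples, and they give no batch or harvest date. On the first principal component, which held 39.1% of the variance, both untreated hearts lay at positive scores (17.4 and 13.4) and all 4 treated hearts at negative ones (-4.15 to -11.2).

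The first comparison asked what the factor Xa inhibitor changed in these hearts. Rivaroxaban-treated hearts had higher mRNA of 9 of 17 glucocorticoid targets, 12 of 25 immediate early genes and 3 of 15 heat shock proteins, and lower mRNA of 8 of 12 markers of the mesothelium, the cell layer that covers the heart. None of these lists passed with an estimated correlation. Sgk1, a serum- and glucocorticoid-regulated kinase, rose from 5.51 ± 0.10 to 6.69 ± 0.01 log2 CPM (SD, n = 2 each), a 2.26-fold rise (log2 1.18, SE 0.08, limma adjusted p = 5.87e-05). Klf2 and Klf4, transcription factors best known from endothelial cells and from reprogramming, rose 1.995-fold and 2.13-fold (log2 0.997, SE 0.07, and log2 1.09, SE 0.07; limma adjusted p = 5.87e-05 for each). Zbtb16, a zinc finger repressor induced by glucocorticoids, had the largest rise among the named genes, 4.37-fold, from 4.44 ± 0.06 to 6.57 ± 0.37 log2 CPM (SD, n = 2 each; limma adjusted p = 0.00269). Msln, which encodes mesothelin, fell from 4.21 ± 0.11 to 2.98 ± 0.23 log2 CPM (SD, n = 2 each; log2 -1.23, SE 0.13, limma adjusted p = 8.14e-04). On the mm10 (GRCm38) assembly these genes lie on chromosome 10 from 21882184 to 21999903 (Sgk1, ENSMUSG00000019970), on chromosome 8 from 72319033 to 72321656 (Klf2, ENSMUSG00000055148), on chromosome 4 from 55527143 to 55532466 (Klf4, ENSMUSG00000003032), on chromosome 9 from 48654297 to 48836222 (Zbtb16, ENSMUSG00000066687) and on chromosome 17 from 25748613 to 25754378 (Msln, ENSMUSG00000063011), and all are annotated as protein-coding.

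Of 17 tested glucocorticoid targets, 9 rose, 1 fell and 7 did not pass over all genes; adjusted over the list alone, 13 rose and 1 fell. The median log2 change was 0.92. Besides Sgk1 and Zbtb16, Ddit4, an inhibitor of mTORC1 signalling, rose 2.43-fold, Errfi1, a feedback inhibitor of the EGF receptor, 2.27-fold, and Tsc22d3, which encodes the glucocorticoid-induced leucine zipper protein, 1.90-fold. The member that fell was Lcn2, which encodes the iron-trapping protein lipocalin-2 and is also a neutrophil marker (log2 -0.95, adjusted p = 0.0281). The list passed camera (adjusted p = 1.89e-14), with adjusted p = 0.338 with an estimated correlation. 8 of its 17 members stand in another list as well.

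Of 25 tested immediate early genes, which cells switch on within minutes of a stimulus, 12 rose and none fell over all genes; adjusted over the list alone, 15 rose and 1 fell. The risers were Klf2, Klf4, Fosl2 (1.81-fold), Atf3 (2.42-fold), Nr4a1 (3.04-fold), Nr4a3 (2.92-fold), Jun, Ier5, Klf6, Btg2, Zfp36 and Maff. Egr1, Fos and Fosb, which respond to growth factors, had log2 changes of -1.37, -0.59 and -0.44 that did not pass over all genes, and Egr1 was the member that fell adjusted over the list alone. The list passed camera at adjusted p = 3e-09, against adjusted p = 0.211 with an estimated correlation. Of 15 heat shock proteins, which help other proteins fold, 3 rose over all genes and 12 did not pass; adjusted over the list alone, 10 rose and 1 fell. Hsph1 rose 1.47-fold, Dnajb1 1.74-fold and Dnaja1 1.57-fold (camera adjusted p = 8e-06 for the list; adjusted p = 0.692 with an estimated correlation). Hspa1b had a log2 change of 1.12 that did not pass (adjusted p = 0.0677), and its reads can be shared with its near-identical copy Hspa1a.

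Of 12 tested mesothelial and epicardial markers, 8 fell, 1 rose and 3 did not pass over all genes; adjusted over the list alone, 11 fell and 1 rose. The median log2 change was -0.96. Krt18 and Krt19, keratins of epithelial layers, fell to 0.365 and 0.366 of the untreated level, Upk3b, a uroplakin found on mesothelium, to 0.524 and Gpm6a to 0.604. Wt1, a transcription factor of the epicardium that is also made by some endothelial cells after injury, rose (log2 0.47, adjusted p = 0.0289). The list passed camera at adjusted p = 1.57e-10, against adjusted p = 0.338 with an estimated correlation.

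4 further lists passed camera with small shifts; none of them held with an estimated correlation, and each lost its call without at least 1 of the 6 libraries; all but the apoptosis list also lost it under another filter or scaling. Nuclear genes of oxidative phosphorylation had a median log2 change of -0.06 (from -0.10 to -0.02 with 1 library left out) over 37 members, none of which passed singly (adjusted p = 0.00115, and adjusted p = 0.836 with an estimated correlation). Its lowest p belonged to Cycs, with a log2 change of -0.22. Contractile and calcium-handling genes had a median of -0.05 over 25 members (adjusted p = 0.0404, and adjusted p = 0.641 with an estimated correlation). 1 of them passed: Kcnj2, which encodes an inward rectifier potassium channel, fell to 0.608 of the untreated level (log2 -0.72, SE 0.07, adjusted p = 8.44e-04). Of 20 apoptosis and p53 targets, Cdkn1a, which encodes a cell cycle inhibitor, rose 1.90-fold and Bcl2l1, which encodes a protein that blocks apoptosis, 1.57-fold (list adjusted p = 0.0188, and adjusted p = 0.554 with an estimated correlation). Erythroid markers had a median of 0.24 (0.16 to 0.39 with 1 library left out) over 7 members with none passing (adjusted p = 0.0387, and adjusted p = 0.54 with an estimated correlation). Their untreated libraries differed widely: Slc4a1, the anion exchanger of red cells, had an SD of 1.16 on the log2 scale between them.

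Outside the lists, Sik1, a salt-inducible kinase, rose 3.31-fold, Fam107a 3.04-fold, Tnfrsf25, which encodes a death receptor, 2.51-fold, and Otud1, a deubiquitinase, 2.40-fold. Drd2, Cntn2 and Ms4a4a, all at low level in untreated hearts, rose 2.61-fold, 2.50-fold and 2.43-fold. The largest fall was that of Cyp26b1, which degrades retinoic acid (log2 -2.58, SE 0.41, adjusted p = 0.00878); its untreated libraries differed by an SD of 1.24, and its log2 change lay between -3.46 and -1.71 with 1 library left out. Cd247, the zeta chain of the T cell receptor, fell to 0.408 of the untreated level. Rrad, a GTPase that restrains calcium channels, fell to 0.423 and the kinase anchor Akap5 to 0.404. Chrdl1, Nkain4, Slc26a3 and Tmprss13, each with fewer than 200 reads per library, fell to between 0.362 and 0.435.

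The series title names inflammation. None of the inflammatory lists passed in this comparison. Cytokines and chemokines, with 12 of 36 genes tested, had a median log2 change of -0.17 and missed the threshold narrowly (camera adjusted p = 0.0501). Csf1, the macrophage growth factor, and Cxcl14 were its 2 called members (log2 -0.71 and -0.74). Adjusted over the list alone, 4 members fell and 0 rose. Tnf lay below the filter and was not tested, with a mean of 1.21 CPM in untreated hearts and 0.436 CPM with rivaroxaban. The NF-kB list had a median of 0.02 (adjusted p = 0.31), with rises of Nfkbia and Tnfaip2, and monocyte and macrophage markers a median of -5.30e-04 (adjusted p = 0.9996). Neutrophil markers, with 5 of 20 tested, had adjusted p = 0.166. Of the receptors and regulators of coagulation named beforehand, 5 are given, and none of these passed: Thbd, which encodes thrombomodulin, had a log2 change of 0.20 (adjusted p = 0.194), the thrombin receptor F2r 0.19 (adjusted p = 0.247), tissue factor F3 0.09 (adjusted p = 0.62), F2rl1 0.06 (adjusted p = 0.928) and Procr 0.04 (adjusted p = 0.939). F2 and F10 were not analysed here.

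In all, 319 of 12981 genes passed a limma adjusted p of 0.05, 191 higher and 128 lower, and 53 of these changed at least by a log2 of 1. Without the mean-variance trend in limma no gene passed, with 1938 genes at an unadjusted p under 0.05 and a lowest adjusted p of 0.0578. The count moved to 173 and 61 without rivaroxaban replicates 14 and 15, and to 134 and 212 without untreated replicates 8 and 9.

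**Figure D1:**
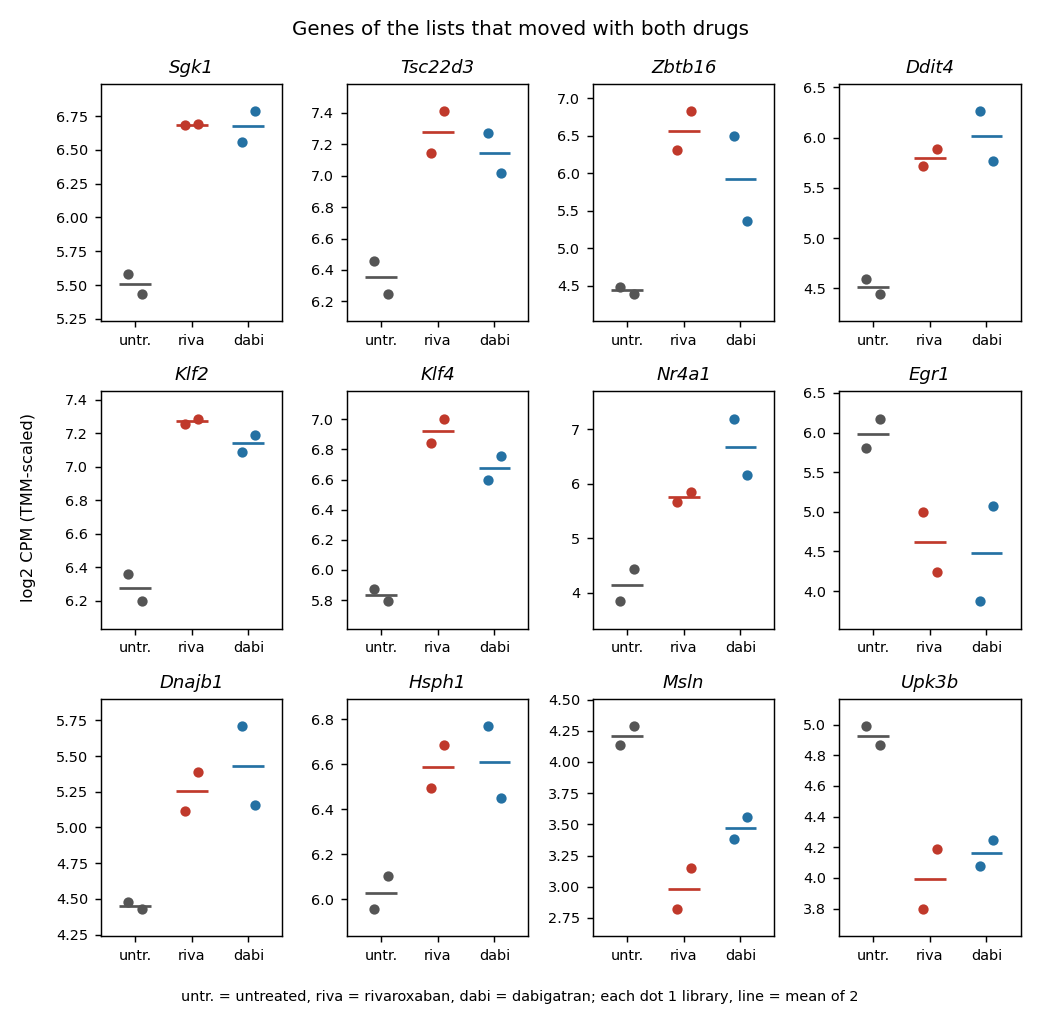
Log2 CPM (TMM-scaled, y axis) of 12 genes in the untreated, rivaroxaban and dabigatran hearts (x axis); each dot is 1 library and each line the mean of 2. For Sgk1 the untreated mean was 5.51, the rivaroxaban mean 6.69 and the dabigatran mean 6.67, and for Msln they were 4.21, 2.98 and 3.47.

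The second comparison asked what the thrombin inhibitor changed. Dabigatran-treated hearts had higher mRNA of 11 of 17 glucocorticoid targets, 5 of 15 heat shock proteins and the nuclear receptors Nr4a1 and Nr4a3, and lower mRNA of Egr1 and 3 of 12 mesothelial markers. No list passed with an estimated correlation. Nr4a3 rose from 0.99 ± 0.18 to 3.89 ± 0.93 log2 CPM (SD, n = 2 each), a 7.46-fold rise (log2 2.90, SE 0.31, limma adjusted p = 0.0013; log2 2.24 to 3.55 with 1 library left out). Nr4a1 rose 5.78-fold, from 4.14 ± 0.42 to 6.68 ± 0.73 log2 CPM (SD, n = 2 each; log2 2.53, SE 0.27, limma adjusted p = 0.00119). These orphan nuclear receptors are induced rapidly by stress signals, and they lie on chromosome 4 from 48045153 to 48086447 (Nr4a3, ENSMUSG00000028341) and on chromosome 15 from 101254269 to 101274795 (Nr4a1, ENSMUSG00000023034) on mm10. Egr1, an early growth response transcription factor (chromosome 18, 34859823 to 34864984), fell from 5.99 ± 0.26 to 4.47 ± 0.85 log2 CPM (SD, n = 2 each; log2 -1.51, SE 0.32, adjusted p = 0.042). With 1 library left out its log2 change lay between -2.12 and -0.91 (adjusted p up to 0.174), and 7 settings ended its call.

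Of 17 glucocorticoid targets, 11 rose and none fell over all genes; adjusted over the list alone, 14 rose and none fell. The median log2 change was 0.86 (camera adjusted p = 2.74e-18, and adjusted p = 0.35 with an estimated correlation). Errfi1 rose 2.61-fold, Ddit4 2.82-fold, Sgk1 2.24-fold, Zbtb16 2.81-fold (log2 1.49, and 0.93 to 2.05 with 1 library left out), Arrdc2 2.53-fold and the clock gene Per1 1.82-fold. The metallothioneins Mt1 and Mt2, which bind zinc, also rose (log2 0.55 and 1.08). Fkbp5, a chaperone partner of the glucocorticoid receptor, had a log2 change of 0.71 that did not pass here (adjusted p = 0.113). Of 15 heat shock proteins, 5 rose and 10 did not pass over all genes; adjusted over the list alone, 12 rose and none fell. Dnajb1 rose 1.97-fold, Dnaja1 1.72-fold, Hsph1 1.49-fold, Hsp90aa1 1.36-fold and Hspa1b 2.57-fold, the last with reads that can be shared with Hspa1a and with a log2 change of 1.36 that ranged from 0.80 to 1.92 with 1 library left out (list adjusted p = 7.21e-11, and adjusted p = 0.661 with an estimated correlation).

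Of 25 immediate early genes, 10 rose and 1, Egr1, fell over all genes; adjusted over the list alone, 13 rose and 2 fell, the other being Fosb. Fosl2 rose 2.09-fold, Atf3 3.07-fold, Klf2 1.82-fold and Klf4 1.80-fold, and Zfp36, which encodes a protein that destabilises cytokine mRNAs, rose by a log2 of 0.69 (list adjusted p = 3.2e-07, and adjusted p = 0.305 with an estimated correlation). Of 12 mesothelial markers, 3 fell (Upk3b, Msln and Gpm6a, to 0.589, 0.599 and 0.667 of the untreated level) and Wt1 rose (log2 0.51); adjusted over the list alone, 9 fell and 1 rose. The median was -0.64 (adjusted p = 1.19e-06, and adjusted p = 0.35 with an estimated correlation).

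4 other lists passed camera, none of them with an estimated correlation. Of 21 endothelial markers, 4 rose: Rgcc 1.58-fold, the water channel Aqp1 1.29-fold, the VEGF receptor Flt1 1.22-fold and the TGF-beta co-receptor Eng 1.19-fold. Their list median was 0.07 (adjusted p = 0.0235, and adjusted p = 0.405 with an estimated correlation), and 0.01 without dabigatran replicate 12 (adjusted p = 0.212). Erythroid markers had a median of 0.34 (0.21 to 0.61 with 1 library left out) over 7 members, of which Slc4a1 rose 4.36-fold (adjusted p = 0.0487) from 7 to 23 reads per untreated library to 68 to 74; its log2 change of 2.12 ranged from 1.30 to 2.95 over the libraries left out, and 10 settings ended its call (list adjusted p = 6.41e-04, and adjusted p = 0.35 with an estimated correlation). Cell cycle genes had a median of -0.19 over 31 members and T, NK and B cell markers one of -0.40 over 6 members, and no member of either passed over all genes (adjusted p = 0.0017 and 0.0227; adjusted p = 0.769 and 0.684 with an estimated correlation). Without dabigatran replicate 10 these medians were -0.03 and -0.11, and neither list passed (adjusted p = 0.195 and 0.344); each was also lost without 1 of the untreated libraries, and the T, NK and B cell list without the filter (adjusted p = 0.266). The lowest p values there belonged to Cenpf (log2 -0.65, and -1.05 to -0.24 with 1 library left out) and to Ighm, the heavy chain of IgM (log2 -0.55).

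Other rises included Sik1 (3.51-fold), Cntn2 (2.95-fold) and Irs2, an adaptor of the insulin receptor (2.72-fold). Other falls included Akap5 (to 0.427 of the untreated level), Rrad (0.523), Sox4 (0.539), the apelin receptor Aplnr (0.573), Sv2a (0.546), Lrrc4b (0.562), Ndnf (0.588), Grhl2 (0.495), Il20rb (0.515) and Chst4 (0.545). The cytokine list had a median of -0.08 (camera adjusted p = 0.235), with a fall of Csf1 (log2 -0.71). Adjusted over the list alone, 3 of its members fell and 1 rose. The NF-kB list had a median of -0.01 (camera adjusted p = 0.959), with rises of Nfkbia and Tnfaip2, and macrophage markers one of -0.01 (camera adjusted p = 0.959). In the NF-kB and macrophage lists the median and the mean were below 0 while the test pointed up. The same 5 coagulation genes did not pass: the log2 change was 0.15 for Thbd (adjusted p = 0.379), -0.16 for F3 (adjusted p = 0.439), 0.08 for F2r (adjusted p = 0.695), 0.07 for Procr (adjusted p = 0.914) and -0.04 for F2rl1 (adjusted p = 0.96).

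In all, 244 genes passed, 179 higher and 65 lower, and 29 changed at least by a log2 of 1 (limma adjusted p of 0.05). Without the mean-variance trend none passed (1728 at an unadjusted p under 0.05), and quantile normalization left 154. The count moved to 98 without dabigatran replicate 10, to 73 without untreated replicate 8 and to 150 without untreated replicate 9.

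The drug effects against the same untreated hearts were then set beside each other. Of the called genes, 112 were higher and 35 lower with both drugs, and none was called in opposite directions. Independent lists of these sizes would share 2.63 and 0.64 genes, and 100 simulated sets of unchanged groups with shared untreated libraries gave 0.11 and 0.16. Those sets called a mean of only 1.42 and 1.48 genes with rivaroxaban and dabigatran, against 319 and 244 here. Their overlap was therefore bound to be near 0. It cannot show how many of the shared calls come from the shared untreated libraries. Across the 12981 genes, which are not independent replicates, the fold changes of the drugs correlated with Pearson r = 0.71 and Spearman rho = 0.64. Shared untreated libraries alone gave r = 0.50 in the simulation, where genes were drawn independently, so its spread may be understated. The covariance was 0.035 against 0.00898 simulated, a difference of 0.026. With each drug set against a different untreated library, so that none was shared, r was 0.39 and 0.37 for the 2 ways of doing so, rho 0.30 and 0.31 and the covariance 0.0236 and 0.0229. In these fits 37 and 40 genes were higher and 3 and 8 lower with both drugs, where independent lists would share at most 0.93, and 2 and 3 were called in opposite directions. The genes called with both drugs included Klf2, Klf4, Sgk1, Errfi1, Ddit4, Sik1, Nr4a1, Nr4a3, Atf3 and Zbtb16 among the rises and Msln, Upk3b, Gpm6a, Akap5, Rrad and Kcnj2 among the falls.

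**Figure D2:**
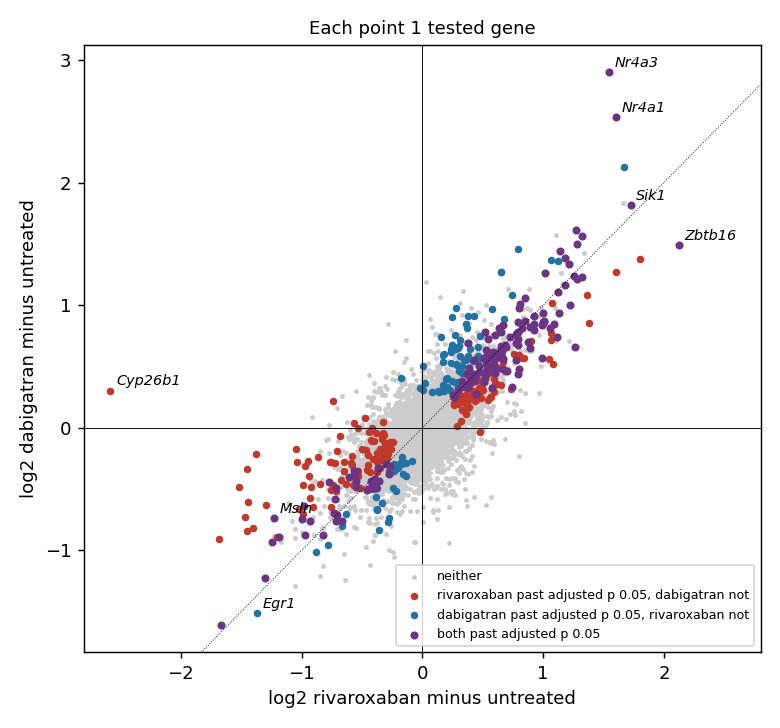
Log2 change of each tested gene with rivaroxaban (x axis) and with dabigatran (y axis), both against the untreated hearts; colours show which comparison passed a limma adjusted p of 0.05 and the dotted line marks equal changes. Called genes lie mostly in the upper right and lower left, with Cyp26b1 (-2.58 with rivaroxaban, 0.30 with dabigatran) away from the line.

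The third comparison asked whether the inhibitors differed from each other, as the title puts it. 10 genes were lower with rivaroxaban than with dabigatran and 0 were higher, by limma at an adjusted p of 0.05, while 1094 genes had an unadjusted p under 0.05. In the 100 simulated sets of unchanged groups, this comparison called 1.6 genes on average and up to 7. Genes were drawn independently of each other in those sets. With correlated genes the count can vary more widely, so the sets cannot show that 10 calls exceed chance. Cyp26b1 differed most, at 0.86 ± 0.34 log2 CPM with rivaroxaban and 3.75 ± 0.02 with dabigatran (SD, n = 2 each; log2 -2.89, SE 0.41, adjusted p = 0.0417), with 43 to 76 reads against 362 to 576. It lies on chromosome 6 from 84571414 to 84593908 (mm10). Abi1, an adaptor of the actin-regulating WAVE complex on chromosome 2 from 22940073 to 23040241, had the lowest p (log2 -0.60, SE 0.06, adjusted p = 0.0147). Cxcl14, a chemokine, was at 0.516 of the dabigatran level and Fah, which completes tyrosine breakdown, at 0.617. Bmp6, a BMP ligand, was at 0.655, Ccdc171 at 0.698 and the sodium channel Scn4a at 0.703 (adjusted p between 0.0147 and 0.0447 for the genes given). Zfp970 and Zfp972, at 0.667 and 0.638, belong to a cluster of similar zinc finger genes on chromosome 2 whose reads can be split between copies, so their values are uncertain. Against untreated hearts, Abi1, Ccdc171, Cxcl14 and Cyp26b1 fell with rivaroxaban, while Zfp970 rose with dabigatran. The 6 genes with the smallest p in the other direction did not pass: Slc7a1 (log2 0.41, adjusted p = 0.0689), Cep128 (0.52), Otud1 (0.60), Id1 (0.32), Rin3 (0.42) and Muc6 (0.75).

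**Figure D3:**
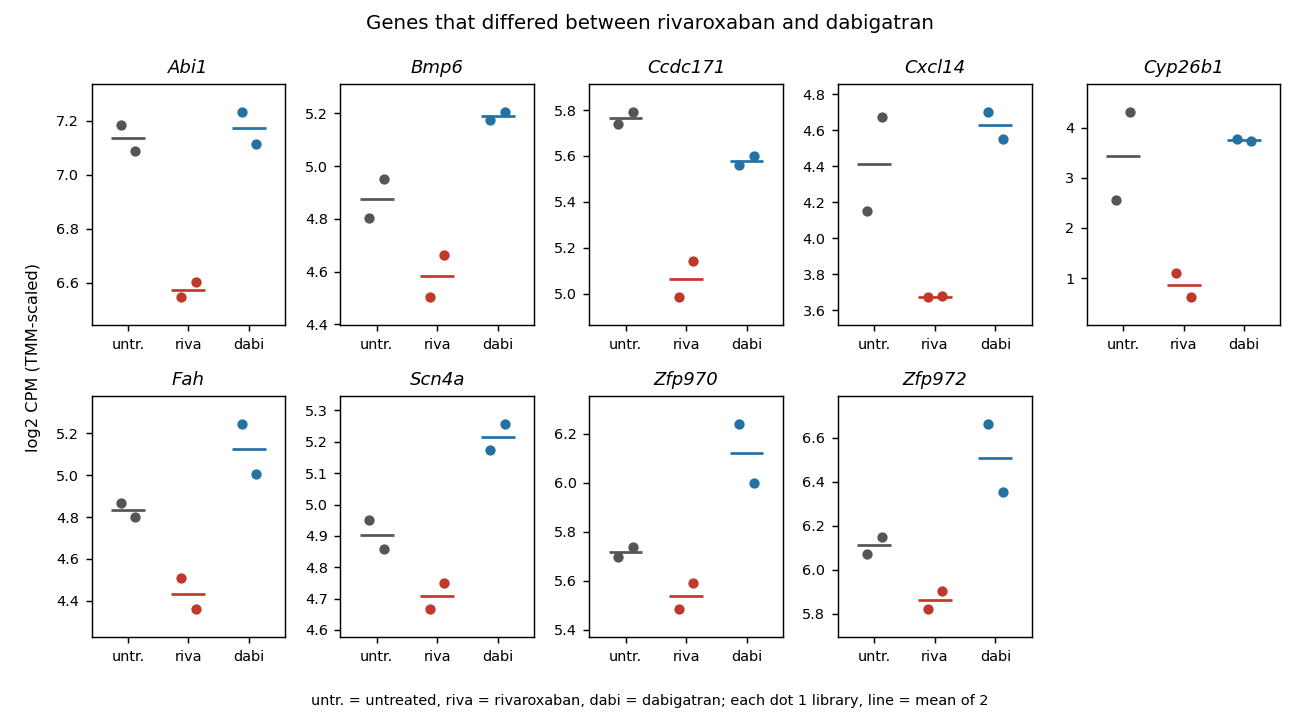
Log2 CPM (TMM-scaled, y axis) in the 3 groups (x axis) of 9 genes called between rivaroxaban and dabigatran; each dot is 1 library and each line the mean of 2. In all 9, both rivaroxaban libraries lie below both dabigatran libraries, as for Cyp26b1 with means of 0.86 and 3.75.

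11 of 36 lists passed camera between the drugs, and none with an estimated correlation, where the lowest adjusted p was 0.672. Cell cycle genes had the largest shift, a median log2 difference of 0.37, higher with rivaroxaban, with 29 of 31 members positive. None was called over all genes, and 2 were higher adjusted over the list alone (Ccnd1 at log2 0.42 and Cenpf at 0.87). The list had camera adjusted p = 2.87e-08, and adjusted p = 0.672 with an estimated correlation. With 1 library left out, Ccnd1 ranged from 0.25 to 0.59 and Cenpf from 0.46 to 1.28. The mean log2 CPM of the list was 2.07 in both rivaroxaban replicate 15 and dabigatran replicate 12. It was 2.54 in rivaroxaban replicate 14 and 1.76 in dabigatran replicate 10. Mesothelial markers were lower with rivaroxaban by a median of -0.32, or -0.09 without rivaroxaban replicate 14, with none of 12 members called over all genes and 2, Msln and Krt18, lower adjusted over the list alone (list adjusted p = 1.11e-04, and adjusted p = 0.672 with an estimated correlation). The other higher lists were endoplasmic reticulum and integrated stress genes (median 0.14, and 0.03 with adjusted p = 0.467 without dabigatran replicate 12, lowest p for the chaperone Hspa5 at 0.19), extracellular matrix genes (0.13, lowest p for Col6a2 at 0.33) and coagulation, fibrinolysis and protease receptor genes (0.07, and 0.03 with adjusted p = 0.276 without rivaroxaban replicate 14, lowest p for F3 at 0.26). The other lower lists were nuclear oxidative phosphorylation (-0.07, and -0.11 to -0.04 with 1 library left out, lowest p for Cycs), fatty acid oxidation (-0.08, lowest p for Lpl), oxidative stress genes (-0.09, lowest p for Gsta4), heat shock proteins (-0.11, and -0.18 to 0.04 with 1 library left out, lowest p for Hspd1), fetal and stress cardiomyocyte genes (-0.08, and -0.02 without rivaroxaban replicate 14, lowest p for Mt1) and contractile genes (-0.05, lowest p for Kcnj2), and no member of these 9 lists passed over all genes. Their adjusted p lay between 1.9e-06 (oxidative phosphorylation) and 0.026 (fetal and stress genes), and between 0.672 and 0.704 with an estimated correlation. Adjusted over the list alone, 2 matrix genes (Col6a2 and Fn1) were higher and 1 (Cilp) was lower, and no member of the other 8 passed. Glucocorticoid targets (median -0.05, adjusted p = 0.312), immediate early genes (adjusted p = 0.39, with a median of 0.11 and a mean of -0.00232), cytokines and chemokines (-0.10, adjusted p = 0.312, with Cxcl14 called), the NF-kB list (0.04, adjusted p = 0.216) and macrophage markers (-0.00499, adjusted p = 0.959) did not pass between the drugs. For Sgk1 and Klf2 the drugs differed by log2 0.01 and 0.13.

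**Figure D4:**
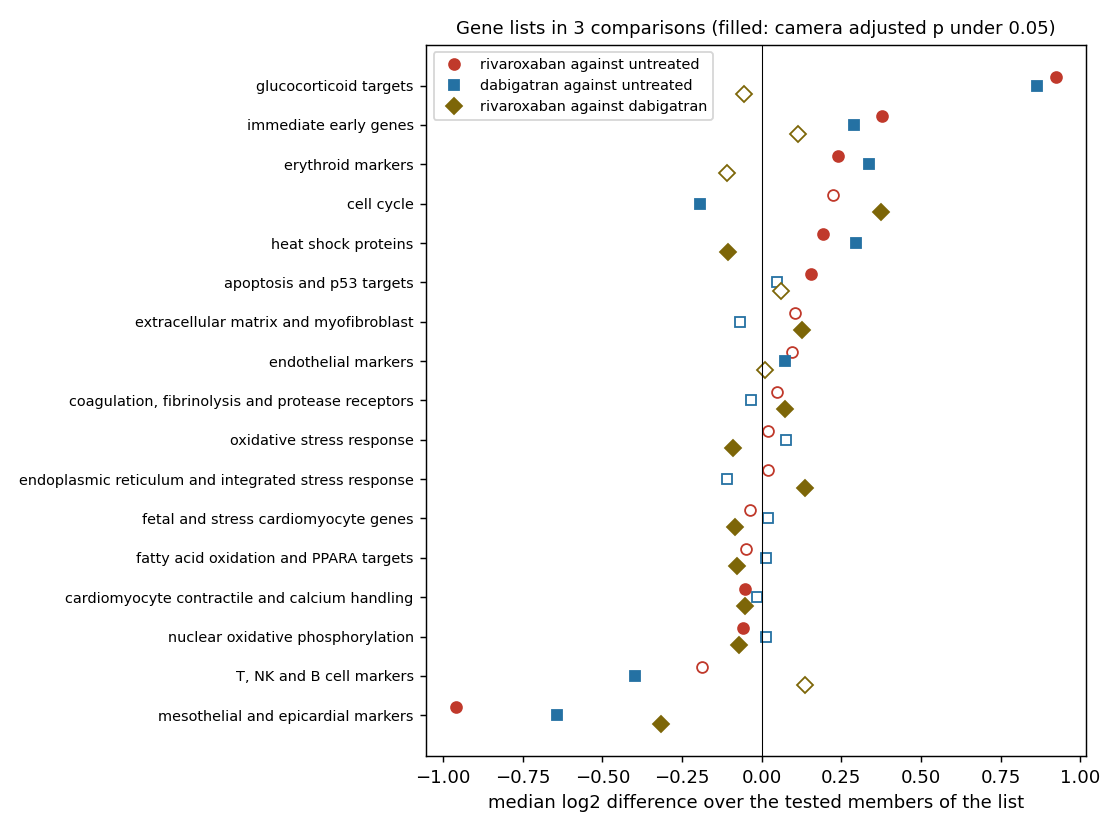
Median log2 difference over the tested members (x axis) of each list that passed in at least 1 of the 3 comparisons (y axis); filled symbols mark a camera adjusted p under 0.05 with the preset correlation. Glucocorticoid targets lie at 0.92 and 0.86 with rivaroxaban and dabigatran against untreated hearts, and mesothelial markers at -0.96 and -0.64.

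None of the calls between the drugs passed without dabigatran replicate 10, rivaroxaban replicate 14 or rivaroxaban replicate 15, which leaves 1 library in a group, while the log2 differences kept their direction (Abi1 from -0.66 to -0.54, Cyp26b1 from -3.13 to -2.64 and Zfp972 from -0.80 to -0.49); 20 passed without dabigatran replicate 12, and 6 without either untreated library; quantile normalization left 1 and limma without the trend 0 (984 at an unadjusted p under 0.05). Of the 11 lists, cell cycle, nuclear oxidative phosphorylation and oxidative stress genes passed whichever library was left out, although oxidative phosphorylation did not pass with quantile normalization (median -0.02, adjusted p = 0.178), and the other 8 each lost their call without at least 1 library; without rivaroxaban replicate 14 the cell cycle median was 0.18, and the mesothelial list (adjusted p = 0.0511), fatty acid oxidation (0.106), heat shock proteins (median -0.03, adjusted p = 0.598) and the matrix list (median 0.00421, adjusted p = 0.993) were among those lost.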

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

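The tests of the clock genes and of the scaling below were written before their own values were seen, although the changes of some clock genes were known by then; all others were chosen after the result was seen.

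A direct test of the drugs against each other singled out genes with these log2 differences of rivaroxaban minus dabigatran: Cyp26b1 -2.89, Cxcl14 -0.96, Fah -0.70, Zfp972 -0.65, Bmp6 -0.61, Abi1 -0.60, Zfp970 -0.58, Ccdc171 -0.52 and Scn4a -0.51. The same test singled out 11 lists, with these median log2 differences: cell cycle 0.37, endoplasmic reticulum and integrated stress 0.14, extracellular matrix 0.13, coagulation and fibrinolysis 0.0727, mesothelial and epicardial markers -0.32, heat shock proteins -0.11, oxidative stress -0.0885, fetal and stress cardiomyocyte genes -0.0832, fatty acid oxidation -0.0785, nuclear oxidative phosphorylation -0.0714 and contractile genes -0.0529. None of these lists passed with an estimated correlation, where the lowest adjusted p was 0.672. The drugs were given at different doses, so the drug and its dose cannot be separated.

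Glucocorticoid, immediate early and heat shock lists were higher with both drugs: of their 56 tested members, 24 rose and 1 fell with rivaroxaban, and 26 rose and 1 fell with dabigatran. None of the lists passed with an estimated correlation (adjusted p = 0.338, 0.211 and 0.692 with rivaroxaban and 0.35, 0.305 and 0.661 with dabigatran). A single deviating untreated library is argued against, since the median over all 56 members stayed at 0.46 or above for each drug against either untreated library alone. A higher share of endothelial cells is argued against as well: the median endothelial change was at most 0.215 of the median over all 56 members (0.09 against 0.44 with rivaroxaban and 0.07 against 0.46 with dabigatran, with an SD of 0.19 and 0.24 over endothelial markers). Only 1 and 2 of 21 endothelial markers had a log2 change at or above that median, counted whether or not they passed. The endothelial list passed camera with dabigatran (adjusted p = 0.0235, and 0.405 with an estimated correlation), so a small rise in share is not excluded. The values argue only against a rise large enough to carry the pattern. The limit for that ratio was written after the values were seen, and the rivaroxaban ratio of 0.215 met it narrowly. A different time of day at harvest stays open, because the shift of clock output against opposite-phase genes was -0.19 with a 95% interval from -1.19 to 0.81, too wide to decide. A difference in handling, stress or batch between untreated and treated hearts stays open too, since 0 label fields give a batch, date or harvest order, and so does an effect of the drugs themselves, which this design cannot separate from it.

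The list of mesothelial and epicardial markers was lower with both drugs, with 8 of 12 members called lower with rivaroxaban, 3 with dabigatran and Wt1 called higher with each. It did not pass with an estimated correlation (adjusted p = 0.338 and 0.35). As for the authors' scaling, the median stayed at -0.64 or lower under quantile normalization and equal medians for both drugs. These rescalings moved the median of all tested genes by at most 0.0171, so the outcome was close to fixed beforehand. It shows only that neither rescaling removes the pattern. Less surface tissue in the treated samples stays open: 91.7% of the tested markers, 11 of 12, were lower in all 4 treated libraries than in both untreated ones, which restates the pattern and would hold as well if the drugs acted on the surface layer.

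The cell cycle list was higher with rivaroxaban than with dabigatran by a median of 0.37, with none of 31 members called over all genes and adjusted p = 0.672 with an estimated correlation. Without rivaroxaban replicate 14 the median was 0.183, narrowly below the limit of 0.187 (0.5 of the full value) set for this test, and the list still passed (camera adjusted p = 0.0238). Without dabigatran replicate 10 it was 0.23, so 1 deviating library may carry much of the difference. Without rivaroxaban replicate 15 it was 0.59 and without dabigatran replicate 12 it was 0.50. The mean log2 CPM of the list was 2.54 in rivaroxaban replicate 14 and 1.76 in dabigatran replicate 10. It was 2.07 in both rivaroxaban replicate 15 and dabigatran replicate 12, and 2.31 and 1.997 in untreated replicates 8 and 9. On these means the difference came from 1 library of each drug group, replicates 14 and 10. Leaving out 1 library at a time keeps 1 of them and cannot show this. A difference between the drugs stays open.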

How the results depend on the processing

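Of the settings below, voom on recovered reads and the split of the untreated libraries were chosen only after the data were seen. Limma without the trend, whose prior degrees of freedom were 2.51 in place of 7.75, called 0 genes in each of the 3 comparisons. At an adjusted p of 0.10 the counts were 634, 463 and 20 for rivaroxaban and dabigatran against untreated and for the drugs against each other. Quantile normalization left 154 for dabigatran against untreated and 1 between the drugs, and a fit of only the 4 libraries compared left 6 between the drugs; the cause was not tested. The other filters, scalings and priors kept each count within 1.5 times of the main one, and voom gave 314, 235 and 8, with 303, 223 and 8 of the main calls among them. Over the libraries left out in turn, the counts ranged from 61 to 410, from 73 to 270 and from 0 to 20; a group left with 1 library is assumed to vary like the others. For lists, the estimated correlation left 0 in each comparison, fry 1, 1 and 0, and quantile normalization 7 between the drugs. Leaving out libraries gave 4 to 14, 8 to 12 and 6 to 17 lists. Among those that passed, 4 of the 8 with rivaroxaban, 3 of the 8 with dabigatran and 8 of the 11 between the drugs lost their call in at least 1 case. The glucocorticoid, immediate early, heat shock and mesothelial lists passed against untreated for both drugs with every library left out and under each filter and quantile normalization. The correlation of the drugs' fold changes ranged from 0.60 to 0.78 with libraries left out, and from 0.64 to 0.76 with Spearman's rho, other filters and quantile normalization. With no untreated library shared it was 0.39 (rivaroxaban against replicate 8, dabigatran against 9) and 0.37 (the reverse), as the shared part is then removed and each control is 1 library. No named gene that was called changed direction in any setting. Under the omission of a library, 16 of 37 named calls for rivaroxaban, 11 of 39 for dabigatran and 0 of 9 between the drugs passed in every case. Direction changed only in genes that had not been called, and in the heat shock and matrix lists between the drugs, which passed with all libraries but not where the direction changed. They are given as ranges over the libraries left out. With rivaroxaban against untreated these were F2rl1 from -0.21 to 0.324 and Procr from -0.0647 to 0.145. With dabigatran against untreated F2rl1 ranged from -0.31 to 0.224. Between the drugs they were Hspe1 from -0.222 to 0.00306, Thbd from -0.0685 to 0.17, Procr from -0.133 to 0.0767 and the heat shock median from -0.179 to 0.0433. The matrix list median ranged from 0.00421 to 0.24, and without rivaroxaban replicate 14 its test pointed the other way. No paired analysis was possible because the groups share no replicate numbers. With a median of 594 to 975 reads per tested gene, counting depth limits mainly the low genes.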

Other observations

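The levels and terms below were looked at after the data were seen. Among genes raised by rivaroxaban, 27 of 2729 Gene Ontology terms passed (one-sided exact Fisher test, Benjamini-Hochberg adjusted p of 0.05), and 10 passed for dabigatran. The lowest adjusted p belonged to neuron differentiation with rivaroxaban, with 11 rises where 1.02 were expected (adjusted p = 1.25e-05). With dabigatran 3 terms shared the lowest adjusted p of 0.00764: tau protein binding, with Apoe, Clu, Hsp90aa1, Picalm and Sgk1, negative regulation of DNA-binding transcription factor activity, with 7 genes, and negative regulation of myeloid cell differentiation. Angiogenesis, the next term with rivaroxaban, held 16 of the 183 annotated rises with rivaroxaban where 2.77 were expected (adjusted p = 2.29e-05), among them Vegfa, Notch1, Epha2, Gja5, Robo4, S1pr1, Hey1 and Eng. With dabigatran it held 10 where 2.54 were expected and did not pass (Fisher adjusted p = 0.0522), and the difference between the drugs was not tested. Terms of the opposite sense passed too. With rivaroxaban, negative regulation of angiogenesis held 6 rises, among them Klf4 and Epha2 (Fisher adjusted p = 0.0395). With dabigatran, negative regulation of endothelial cell proliferation held Apoe, Atoh8, Eng and Rgcc (Fisher adjusted p = 0.0479). The terms therefore give no direction for vessel growth. Negative regulation of myeloid cell differentiation passed for both drugs with 5 genes each, Gata2, Nfkbia, Rbm15, Zbtb16 and Zfp36 (adjusted p = 0.00502 and 0.00764). No term passed among the falls of either drug.

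2 members of the circadian list moved alike with both drugs: Per1 rose by a log2 of 0.79 and 0.86, and Bhlhe41, a repressor within the clock, changed by -0.45 and -0.50 (adjusted p = 0.00595 and 0.00555). Dbp, a clock output gene, fell with dabigatran by 0.56 on the log2 scale (adjusted p = 0.037). The list as a whole did not pass for either drug (adjusted p = 0.934 and 0.708), and with dabigatran its median was above 0 while its test pointed down. Kcna5, a potassium channel of atrial and vascular muscle, rose with both drugs by a log2 of 1.01 and 0.87 (adjusted p = 5.87e-05 and 1.25e-04).

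Several genes that are usually abundant in freshly infarcted heart were near the floor in every group. Spp1, which encodes osteopontin, lay between 0.247 and 0.632 CPM in the 6 libraries (8 to 23 reads), S100a8 between 0.309 and 0.548 CPM, S100a9 between 0.187 and 0.577 CPM and Il1b between 0.261 and 0.664 CPM. Postn had a mean of 60.4 CPM in untreated hearts and Col1a1 one of 204.8, against 38549 for the cardiac myosin gene Myh6. At these levels, the results for the inflammatory, neutrophil and matrix lists may not describe freshly infarcted tissue. 12 of the 36 listed cytokine and chemokine genes were tested. Tnf had a mean of 1.21 ± 0.03 CPM in untreated hearts, 0.436 ± 0.278 with rivaroxaban and 0.469 ± 0.082 with dabigatran (SD, n = 2 each), below the filter and not tested.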
